A study of Mus musculus with 5 samples.

How the data were processed

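RNA of whole mouse embryos of the C57BL6J strain at gestation day 9.5 was measured on 5 Affymetrix Mouse Genome 430A arrays, which carry 1 colour and a biotin label. The labels put 3 arrays in the Folr1+/+ group and 2 in the Folr1-/- group. Per the labels' protocols, Folr1-/- embryos came from crosses of Folr1+/- parents with the dams on a diet with added folate. The diet of the dams of the Folr1+/+ embryos is not stated separately, so diet and genotype cannot be told apart if it differed. The embryos were freed of decidua, chorion and amnion and genotyped by PCR, and the yolk sac is not mentioned there. RNA was amplified in 2 rounds, which favours the 3' ends of transcripts. The labels call the arrays of a group biological replicates, but do not say whether an array holds 1 embryo or a pool. The p-values of single genes measure the spread between these arrays.

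The deposited values are MAS5 signal intensities per probe set on a linear scale, per the submitters' processing notes, with the MAS5 version not given in the sources used here. The authors' scaling left the mean signal, after trimming 2% at each end, at 150.06 or 150.07 on every array. The median signal was 35.2, 38.3 and 35.7 in the Folr1+/+ replicates and 33.3 and 33.0 in the Folr1-/- replicates, and this scaling was kept. Detection calls of the arrays were not used here, so a dim signal could not be told from background probe set by probe set. The small number of arrays limits the precision, with 3 residual degrees of freedom per gene.

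The table held 22690 probe sets, of which 64 were controls. Of the others, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 were not listed there. No symbol needed an update against the gene table of assembly GRCm38.p6, which served only for gene names, chromosomes and the order of neighbouring genes. Each of 12393 genes was represented by its probe set with the highest mean log2 signal over all 5 arrays, and 4956 genes had more than 1 probe set. Genes under the 40th percentile of mean log2 signal were left out, which removed 4957 genes and left 7436.

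Signals were tested as log2(signal + 16) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the 7436 genes and an adjusted p threshold of 0.05. Fold changes are therefore on the log2(signal + 16) scale, are given as Folr1-/- minus Folr1+/+ with the standard error (SE), and understate the change of dim genes. Before the data were examined, 37 gene lists were fixed. They cover folate and nucleotide metabolism, stress, energy and sterol metabolism, embryonic and extraembryonic tissues, signalling pathways, Hox genes, imprinted genes, genes near Folr1 and sex-linked genes. The 32 lists with at least 5 tested genes, other than the sex-linked genes, were tested with camera (2-sided, preset correlation of 0.01) and adjusted over these lists. Each list was also tested with the correlation estimated from its own genes, with fry, and by its median against 10000 random lists matched on mean expression in 20 bins. For each list, the calls adjusted over the list alone are given beside those over all genes. With the preset correlation, the camera p-value is measured against the spread between genes, not between arrays. The random lists, Fisher's exact tests and the intervals of ratios also take genes as units, though genes vary together on the same 5 arrays.

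The text names, in each direction, the 15 genes with the largest fold change among those past the threshold whose groups do not overlap. Per list it names at most 4 members past the threshold by size of change, or else up to 3 with the smallest unadjusted p. Folr1, the sex-linked genes and the genes near Folr1 with an unadjusted p under 0.05 complete the rule, which took 117 genes. Further list members named beside their counts, such as Trp63, Lrp2, Cryab, Gata4, Hand1, Tnnc1, Mthfd1, Plac1, Prl8a2, Mest and Otx2, were chosen after their values were seen. Among the 108 genes past the threshold, 50 had more than 1 probe set. In 7 of these (Afp, Cdx2, Hoxb4, Myh6, Ndufb9, Pax6 and Trp53inp1) 8 probe sets went the other way, and the highest group mean among those probe sets was a signal of 16.1. Probe sets of the embryonic globins, of Eif2s3y and its X-linked copy, and of keratins with pseudogenes can share sequence, so the level of each such gene is uncertain.

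The same code was tested on simulated arrays, 2 against 3, at the means and spreads of the 7436 genes, with 200 genes changed. It recovered 0% of genes changed by 0.5 on the log2 scale, 80% of those changed by 1 and 100% of those changed by 2, and called 0 unchanged genes. These rates do not carry over to the data. There 1114 genes changed, against 200 in the simulation, and with more changed genes the adjusted p threshold is less strict. The simulated noise was also independent between genes. Calls near 0.5 did occur in the data, such as Phgdh at 0.52. Alternatives fixed beforehand were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, centring on the array median, no intensity trend, array weights, the mean of a gene's probe sets, all probe sets, the replicate number as a block, the Actb 3'/5' ratio as a covariate, an adjusted p threshold of 0.1, and leaving out each array in turn. Leaving out the X- and Y-linked genes was added after seeing the data. Figures were drawn with matplotlib 3.10.9.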

Results

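Gene expression was measured in whole mouse embryos at gestation day 9.5, in 3 Folr1+/+ and 2 Folr1-/- replicates with 1 array each. Folr1 encodes a folate receptor that takes folate into cells by endocytosis, and the comparison asks which transcripts differ between embryos with and without it. Correlations of log2 signals over genes were 0.971 to 0.982 within the Folr1+/+ group, 0.980 between the Folr1-/- arrays and 0.926 to 0.949 between the groups. The first principal component held 64.6% of the variance and separated the groups. The Actb 3'/5' ratio, which rises as RNA is shortened, was 21.1, 39.5 and 29.1 in the Folr1+/+ replicates and 30.5 and 22.8 in the Folr1-/- replicates. Folr1+/+ replicate 2 also had the highest spike-in control signal, with a geometric mean of 703 against 248 to 375 on the other arrays.

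The signal of Folr1 itself did not differ between the groups. It was 57.0, 50.01 and 40.2 in the Folr1+/+ replicates (49.1 ± 8.44, SD, n = 3) and 50.2 and 41.8 in the Folr1-/- replicates (46.0 ± 5.95, SD, n = 2). The log2 fold change was -0.07 ± 0.20 (SE), with a limma adjusted p of 0.858. The mean of Folr1 lay at the 47.9th percentile of all genes. Which part of the gene the targeted allele removes is not given in the sources used here, so this probe set does not check the genotype. The arrays are therefore called by their labels, and every direction given here rests on those labels.

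Sex-linked genes separated the groups. Xist, transcribed from the inactive X chromosome of females, had signals of 29.4, 35.7 and 25.0 in the Folr1+/+ replicates and 419 and 770 in the Folr1-/- replicates (log2 fold change 3.67 ± 0.24, SE, adjusted p = 5.0e-06). The Y-linked Eif2s3y had signals of 300.3, 345 and 372 against 104 and 3.13 (-2.88 ± 0.53, adjusted p = 0.0035). The Y-linked Kdm5d had signals of 120, 89.5 and 107 against 25.2 and 0.796 (-2.20 ± 0.31, adjusted p = 0.00070). Folr1-/- replicate 1 thus carried both Xist and Y-linked signal. Without Folr1-/- replicate 2 the fold change of Eif2s3y was -1.56. Of the X-linked genes tested, 21.0% changed, against 14.7% of autosomal genes (Fisher's exact test, 2-sided, p = 0.0085), and 1057 of the 1109 changed genes with an X-linked or autosomal position were autosomal. Without the X- and Y-linked genes, a setting chosen after seeing the data, 1053 of 7186 genes changed.

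Genes of the visceral endoderm and of epithelia were higher in the arrays labelled Folr1-/-, and genes of primitive red blood cells, neural progenitors, neural crest and somites were lower. As lists these passed camera with its preset correlation, and none passed with an estimated correlation (lowest adjusted p = 0.11 with an estimated correlation). Afp, a serum protein of the yolk sac and fetal liver, had a signal of 2733 ± 291 (SD, n = 2) in the Folr1-/- arrays and 454 ± 94.2 (SD, n = 3) in the Folr1+/+ arrays. The embryonic globin gene Hbb-y had signals of 28.4 and 358 in the Folr1-/- arrays and 3785 ± 523 in the Folr1+/+ arrays. Of 7436 genes tested, 1114 changed, 609 of them higher and 505 lower in the arrays labelled Folr1-/-. A log2 fold change of at least 1 was seen in 343 of these, 242 higher and 101 lower. The groups did not overlap in any of the 1114 genes, and they did not overlap in 46.7% of all tested genes, where chance gives 20%. With each array centred on its median, 769 genes were higher and 341 lower, so that 69.3% of the changed genes were higher in place of 54.7%. The count fell to 636 without Folr1+/+ replicate 3, 369 without Folr1-/- replicate 1 and 664 without Folr1-/- replicate 2, of which 625, 353 and 590 were among the 1114.

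Of the 32 gene lists tested, 14 passed the threshold, 5 higher and 9 lower in the arrays labelled Folr1-/-. With an estimated correlation between the genes of a list, 0 lists passed, and the lowest adjusted p was 0.11, while fry, which tests whether a list's genes move one way on balance, gave 18. Those 18 leave out the p53 list and add imprinted (fry adjusted p = 0.011), hedgehog (0.031), pharyngeal arch (0.038), tail bud (0.047) and WNT genes (0.047), none of which passed camera. The calls of 9 lists held at every other setting in which they were tested (endoderm, epithelium, erythroid, neural progenitor, somite, cholesterol, oxidative phosphorylation, glycolysis and BMP), and the erythroid and somite lists had too few genes for a test with the filter at the 60th percentile. With the mean of a gene's probe sets, fold changes were smaller for Afp (1.37), Cdkn1a (1.20), Gas1 (-0.80), Scd1 (-1.07), Sox10 (-1.49), Sox17 (1.07) and Tbx3 (0.63). With it 12 calls of named genes were lost, among them those of Myh6 (-0.43), Trp53inp1 (0.54), Pdia4 (0.43), Phgdh (0.50) and Stard10 (0.83). Among other genes, calls were also lost for Ctps, Fzd3, Mcm5, Nnat, Pdia4, Phgdh, Stard10 and Tfap2a with no filter, for Fzd3, Mcm5 and Tfap2a with median centring, for Ctps, Mcm5, Phgdh and Stard10 with no intensity trend, for Ctps, Fzd3, Phgdh and Tfap2a with the replicate number as a block, and for Stard10 with quantile normalization and a pseudocount of 1. With a pseudocount of 64, the medians of the cholesterol, erythroid, somite and anterior Hox lists were -0.47, -0.68, -0.73 and -0.26, and with no filter that of the somite list was -0.44. Some genes with a dim signal in a Folr1-/- array had smaller fold changes with 64 as well: Pax6 -1.10, Hes5 -1.345, Zic1 -1.61, Nr2f1 -1.63, Ebf3 -0.59, Sox10 -1.43, Sox9 -0.70, Pax3 -0.73, Tcf15 -0.95, Myl2 -1.32, Nppa -0.89, Nnat -0.68, Eif2s3y -1.92 and Kdm5d -1.155. With a pseudocount of 1, Sox10 had -4.35 and Kdm5d -3.95, so the sizes of these changes depend on the pseudocount while their calls do not.

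**Figure D1:**
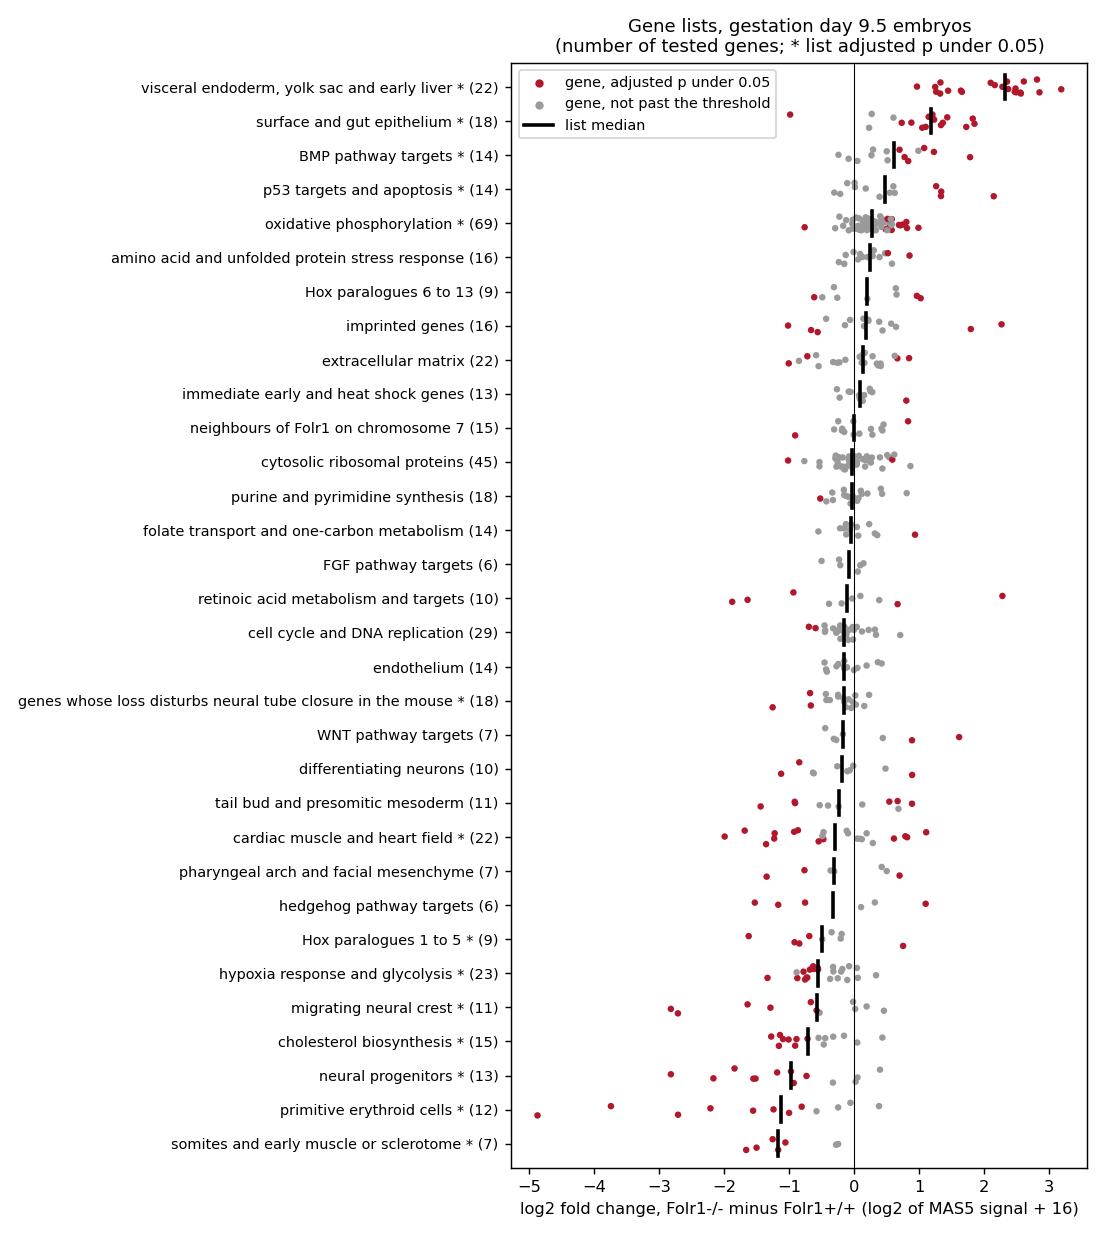
Log2 fold change (Folr1-/- minus Folr1+/+, log2 of MAS5 signal + 16) on the horizontal axis for the tested genes of 32 lists on the vertical axis, with the number of tested genes in brackets. Each point is a gene, red where its adjusted p is under 0.05 and grey otherwise, black bars are list medians, and a star marks a list with an adjusted p under 0.05.

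Every tested member of the list for visceral endoderm, yolk sac and early liver rose, 22 of 22, with 0 lower and a median log2 fold change of 2.31 (camera adjusted p = 1.7e-28, adjusted p = 0.11 with an estimated correlation, 22 adjusted over the list alone). Apolipoprotein genes were among the largest changes, with Apoa4 at 3.18 ± 0.19 (SE), Apom at 2.85 ± 0.16 and Apoa1 at 2.61 ± 0.28. Ttr, a thyroid hormone carrier, had a signal of 5482 ± 978 (SD, n = 2) against 972 ± 167 (SD, n = 3). Cubn and Amn, which form the cubilin uptake receptor, rose by 2.47 ± 0.17 and 2.49 ± 0.24, the protease gene Ctsh by 2.81 ± 0.15 and the protease inhibitor gene Spink1 by 2.56 ± 0.20. The smallest change in the list was that of Lrp2, at 0.96 ± 0.19. Outside the list, large increases were seen for the water channel gene Aqp8 (2.70 ± 0.27), the scaffold gene Pdzk1 (2.65 ± 0.31), the glucose transporter gene Slc2a2 (2.62 ± 0.25), the peptidase gene Dpp4 (2.62 ± 0.18) and the protease gene Lgmn (2.49 ± 0.20). Aqp8 and Pdzk1 had Folr1+/+ signals of 17.5 and 16.4, near the pseudocount of 16, and with a pseudocount of 64 their fold changes were 1.705 and 1.60 and that of Slc2a2 was 2.11. The sex-linked genes differed between the same arrays.

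Of 18 tested genes of surface and gut epithelium, 14 rose, 1 fell and 3 did not pass (median 1.17, adjusted p = 1.3e-10, adjusted p = 0.12 with an estimated correlation, 15 higher and 1 lower adjusted over the list alone). The keratin gene Krt8 had a signal of 3141 ± 45.1 (SD, n = 2) against 952 ± 176 (SD, n = 3), and Krt18 and Krt19 rose by 1.82 ± 0.20 and 1.43 ± 0.20. Sox17, a transcription factor gene of the endoderm, rose by 1.85 ± 0.21. Trp63, a transcription factor gene of stratified surface epithelium, fell by 0.99 on the log2 scale. Trophoblast and decidua had 2 tested genes, too few for a list test, and both rose. They were Plac1, at 1.30 ± 0.16, and Prl8a2, at 1.44 ± 0.38, with signals of 143 and 34.6 in the Folr1-/- replicates and 17.4 ± 5.11 in the Folr1+/+ arrays.

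Primitive erythroid genes were lower in the arrays labelled Folr1-/-, the same arrays in which the endoderm list was higher by a median of 2.31 and the sex-linked genes differed. Of 12 tested genes 8 fell, 0 rose and 4 did not pass (median -1.12, adjusted p = 1.2e-07, adjusted p = 0.11 with an estimated correlation, 0 higher and 9 lower adjusted over the list alone). The embryonic globin genes Hbb-y, Hbb-bh1 and Hba-x had log2 fold changes of -4.87 ± 0.60, -3.74 ± 0.25 and -2.71 ± 0.25, and the red cell anion exchanger gene Slc4a1 -2.21 ± 0.19. The Folr1-/- signals of Hba-x (7.44 and 25.0) and Slc4a1 (11.5 and 7.98) are near the pseudocount, which sets the size of these values, and with a pseudocount of 64 they were -1.66 and -1.18. Endothelial genes gave 0 calls among 14 tested (median -0.15, adjusted p = 0.53, 0 adjusted over the list alone). Their smallest unadjusted p values were those of Tek, Eng and Esam, with fold changes of 0.42 ± 0.17, -0.46 ± 0.21 and -0.43 ± 0.20. Tek passed with the Actb 3'/5' ratio as a covariate (0.48, limma adjusted p = 0.047). The median of the list was -0.046 without Folr1-/- replicate 1, where Tek and Esam had 0.28 and -0.28, -0.26 without Folr1-/- replicate 2 and -0.090 without Folr1+/+ replicate 3. Macrophage and blood progenitor genes had 3 members tested, none past the threshold.

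In the arrays with the higher endoderm genes (median 2.31), neural progenitor genes fell in 9 of 13 tested members, with 0 higher and 4 not passing (median -0.97, adjusted p = 5.1e-07, adjusted p = 0.11 with an estimated correlation, 9 lower adjusted over the list alone). Zic1 had a signal of 8.55 ± 1.21 (SD, n = 2) against 158 ± 19.7 (SD, n = 3), and the Notch target gene Hes5 fell by 2.17 on the log2 scale. The transcription factor genes Pax6 and Sox2 had log2 fold changes of -1.84 ± 0.22 and -1.55 ± 0.19. Of the forebrain and midbrain genes 4 were tested, too few for a list test, and Otx2 and Sfrp2 fell by 1.36 and 2.03 on the log2 scale, while Six3 and Wnt1 did not pass. Over the 16 genes of this list on the array, most of them too dim to test, 15 had a negative fold change (median -0.66). Among differentiating neuron genes 1 rose, 2 fell and 7 did not pass (median -0.19, adjusted p = 0.24, 1 higher and 4 lower adjusted over the list alone). With no filter on dim genes this list passed (adjusted p = 0.0086), within a range of 0.0086 to 0.51 over the settings other than the estimated correlation, and its median was -0.30 without Folr1-/- replicate 1 and -0.096 without Folr1-/- replicate 2. Its Ebf3 fell by 1.13 on the log2 scale. The nuclear receptor gene Nr2f1, outside the lists, had a log2 fold change of -2.58 ± 0.19.

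Migrating neural crest genes, in the arrays with higher endoderm genes (median 2.31) and different sex-linked genes, fell in 6 of 11 tested members, with 0 higher and 5 not passing (median -0.58, adjusted p = 0.00034, adjusted p = 0.12 with an estimated correlation, 1 higher and 7 lower adjusted over the list alone). Sox10 had a signal of 5.12 ± 1.18 (SD, n = 2) against 124 ± 22.4 (SD, n = 3), and Crabp1 and Sox9 had fold changes of -1.64 ± 0.16 and -1.29 ± 0.22. With the filter at the 60th percentile the list did not pass (adjusted p = 0.12, range 9.4e-05 to 0.12). Somite genes fell in 5 of 7 tested members, with 0 higher and 2 not passing (median -1.17, adjusted p = 2.1e-05, adjusted p = 0.11 with an estimated correlation, 5 lower adjusted over the list alone), among them Tcf15 at -1.50 ± 0.18, Pax3 at -1.26 ± 0.18 and Foxc2 at -1.17 ± 0.18. Tail bud genes went both ways, 3 higher, 3 lower and 5 not passing (median -0.24, adjusted p = 0.53, fry adjusted p = 0.047, range 0.047 to 0.68, 3 higher and 4 lower adjusted over the list alone), and the Notch ligand genes Dll1 and Dll3 fell by 1.44 and 0.92 on the log2 scale. The tail bud median was -0.37 without Folr1+/+ replicate 1, -0.15 without Folr1+/+ replicate 2 and -0.12 without Folr1-/- replicate 2. Pharyngeal arch genes had 1 higher, 2 lower and 4 not passing (median -0.31, adjusted p = 0.53, fry adjusted p = 0.038, range 0.038 to 0.63, the same adjusted over the list alone). Prrx1, also 1 of 3 tested limb bud genes, fell by 1.35 on the log2 scale, while Pitx1 and Sall4, the other limb bud genes, did not pass.

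Genes whose loss disturbs neural tube closure in the mouse passed narrowly. Of 18 tested, 3 fell, 0 rose and 15 did not pass (median -0.16, adjusted p = 0.049, adjusted p = 0.28 with an estimated correlation, 3 lower adjusted over the list alone). The 3 were Pax3, Tfap2a and Fzd3, of which Pax3 is also a somite gene and Tfap2a a neural crest gene. The list passed in only 8 of 18 other settings (adjusted p 0.020 to 0.12), and its median lay at the 9.36th percentile of random lists. It did not pass without Folr1+/+ replicate 1 (adjusted p = 0.12), Folr1-/- replicate 1 (0.087) or Folr1-/- replicate 2 (0.054), with pseudocounts of 1 (0.052) and 64 (0.057), with no filter (0.053) or the filter at the 60th percentile (0.12), with median centring (0.052, median -0.07), with array weights (0.056) or without the X- and Y-linked genes (0.050). The calls of Fzd3 and Tfap2a were lost without either Folr1-/- replicate, with fold changes of -0.89 and -0.47 for Fzd3 and -0.55 and -0.79 for Tfap2a. Both were also lost without Folr1+/+ replicate 3 (-0.67 each), and that of Fzd3 without Folr1+/+ replicate 2 (-0.58).

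Cardiac genes split. Of 22 tested, 9 fell, 4 rose and 9 did not pass (median -0.30, adjusted p = 0.049, adjusted p = 0.28 with an estimated correlation, 4 higher and 9 lower adjusted over the list alone). The ventricular myosin gene Myl2 and the natriuretic peptide gene Nppa fell by 1.99 and 1.69 on the log2 scale, and the myosin heavy chain genes Myh7 and Myh6 by 1.36 and 1.23. The 4 that rose were Cryab, Gata4, Hand1 and Tnnc1, of which Gata4 is also a transcription factor gene of the endoderm and Cryab encodes a small heat shock protein. The list passed in only 8 of 18 other settings (adjusted p 0.016 to 0.22). It did not pass without Folr1+/+ replicate 1 (adjusted p = 0.062), Folr1+/+ replicate 2 (0.084) or Folr1-/- replicate 1 (0.087, median -0.19), with a pseudocount of 1 (0.063), with no filter (0.074) or the filter at the 60th percentile (0.22, median -0.12), with quantile normalization (0.060), with array weights (0.062), with the Actb 3'/5' ratio as a covariate (0.052) or without the X- and Y-linked genes (0.050). The endoderm list was higher by a median of 2.31 in the same arrays, which also differed in the sex-linked genes.

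Cholesterol biosynthesis fell in 8 of 15 tested genes, with 0 higher and 7 not passing (median -0.72, adjusted p = 7.6e-06, adjusted p = 0.17 with an estimated correlation, 10 lower adjusted over the list alone), including Msmo1, Idi1, Sqle and Hmgcs1 at -1.28 to -1.10. Scd1, a fatty acid desaturase gene outside the list, fell by 1.86 on the log2 scale. Hypoxia and glycolysis genes fell in 11 of 23, with 0 higher and 12 not passing (median -0.56, adjusted p = 3.1e-05, adjusted p = 0.28 with an estimated correlation, 12 lower adjusted over the list alone). Among them, Pdk1, whose product inhibits pyruvate dehydrogenase, had a fold change of -1.34 ± 0.17, and the lactate dehydrogenase gene Ldha had a signal of 4795 ± 155 (SD, n = 2) against 8861 ± 1080 (SD, n = 3). Without Folr1-/- replicate 1 this list's median was -0.34. Oxidative phosphorylation genes rose in 12 of 69, with 1 lower and 56 not passing (median 0.27, adjusted p = 1.8e-05, adjusted p = 0.11 with an estimated correlation, 14 higher and 1 lower adjusted over the list alone), led by Ndufa5 at 0.99 ± 0.16. The endoderm list was higher by a median of 2.31 in the same arrays, and the sex-linked genes differed there.

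In the arrays in which the endoderm list (median 2.31), the epithelium list (median 1.17) and the sex-linked genes also differed, targets of p53 and apoptosis genes rose in 4 of 14, with 0 lower and 10 not passing (median 0.47, adjusted p = 0.0086, adjusted p = 0.48 with an estimated correlation, 4 higher adjusted over the list alone). The cell cycle inhibitor gene Cdkn1a had signals of 222 and 509 in the Folr1-/- replicates against 64.1 ± 7.48 (SD, n = 3), and Ccng1 had 277 and 527 against 151 ± 6.09. Trp53inp1 rose by 1.34 ± 0.18, and Perp, which is also an epithelial gene, by 1.33 ± 0.21. The list did not pass with fry (adjusted p = 0.099) or without Folr1-/- replicate 2 (0.092, range 0.00016 to 0.099), where the fold change of Ccng1 was 0.81. Its median was 0.23 without Folr1+/+ replicate 3 and with the replicate number as a block, and 0.19 with no filter. BMP pathway targets, in the same arrays with higher endoderm and epithelium genes, rose in 6 of 14, with 0 lower and 8 not passing (median 0.60, adjusted p = 0.00012, adjusted p = 0.12 with an estimated correlation, 8 higher adjusted over the list alone), among them the ligand gene Bmp4 at 1.78 ± 0.25, Tbx3 at 1.22 ± 0.17 and the antagonist gene Bambi at 1.08 ± 0.17.

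Hox paralogues 1 to 5 had 4 genes lower, 1 higher and 4 not passing (median -0.49, adjusted p = 0.0075, adjusted p = 0.17 with an estimated correlation, the same calls adjusted over the list alone), and Hoxc4 fell by 1.63 on the log2 scale. With the filter at the 60th percentile this list did not pass (median -0.21, adjusted p = 0.41, range 0.0016 to 0.41), and without Folr1-/- replicate 2 its median was -0.75. The calls of Hoxa3 (-0.57) and Hoxb4 (-0.41) were lost with the mean of a gene's probe sets. That of Hoxd1 was lost without Folr1+/+ replicates 2 or 3 (0.59 and 0.80). Without Folr1-/- replicates 1 and 2, fold changes were -0.97 and -0.87 for Hoxa3, -0.865 and -0.83 for Hoxb4 and 0.68 and 0.82 for Hoxd1. Hox paralogues 6 to 13 had 2 higher, 1 lower and 6 not passing (median 0.20, adjusted p = 0.53, 4 higher and 1 lower adjusted over the list alone). Their median was 0.36 without Folr1-/- replicate 1, 0.040 without Folr1-/- replicate 2, 0.12 without Folr1+/+ replicate 3 and -0.038 with no filter. Imprinted genes had 2 higher, 3 lower and 11 not passing (median 0.18, adjusted p = 0.29, 4 higher and 3 lower adjusted over the list alone). This list passed with fry (adjusted p = 0.011, range 0.011 to 0.52), and its median lay at the 98.97th percentile of random lists. Phlda2 and Cdkn1c rose by 2.26 ± 0.19 and 1.79 ± 0.15, and Nnat, Grb10 and Mest fell by 1.02, 0.67 and 0.56 on the log2 scale. Phlda2, Cdkn1c and Grb10, which went both ways, are all known to restrain growth. The call of Grb10 was lost without Folr1-/- replicate 1 (-0.57), and that of Nnat there (-0.57) and without Folr1+/+ replicate 3 (-0.94). The endoderm list was higher and the sex-linked genes differed between these arrays.

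Genes of folate transport and one-carbon metabolism did not move as a group. Of 14 tested, only Gldc, of the mitochondrial glycine cleavage system, passed, at 0.93 ± 0.17, with 13 not passing (median -0.06, mean 0.04, camera direction higher, adjusted p = 0.87, 1 higher adjusted over the list alone). Mthfd1, the trifunctional folate enzyme gene, had a fold change of 0.35 ± 0.15 (adjusted p = 0.13). Purine and pyrimidine synthesis had 1 gene lower, Ctps, of 18 (median -0.03, adjusted p = 0.87, the same adjusted over the list alone), and its fold change of -0.52 ± 0.14 lost its call without either Folr1-/- replicate (-0.60 and -0.45) or without Folr1+/+ replicate 3 (-0.51). The median of that list was -0.12 without Folr1-/- replicate 2 and -0.019 without Folr1+/+ replicate 1. Cell cycle and DNA replication had 2 lower, Bub1b and Mcm5, and 27 of 29 not passing (median -0.15, adjusted p = 0.15, 2 adjusted over the list alone). The call of Bub1b was lost without either Folr1-/- replicate (-0.68 and -0.72), and that of Mcm5 without Folr1-/- replicate 2 (-0.37) or without Folr1+/+ replicates 1 or 3 (-0.60 and -0.61).

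The lists that follow did not pass camera. Amino acid and unfolded protein stress genes had 2 of 16 higher, Pdia4 and Phgdh (median 0.24, adjusted p = 0.11, 2 adjusted over the list alone), and the median lay at the 98.89th percentile of random lists. Without Folr1-/- replicate 1 this list passed (median 0.32, adjusted p = 0.039, range 0.039 to 0.37), and its median was 0.10 without Folr1-/- replicate 2 and 0.15 without Folr1+/+ replicate 2, while the calls of both genes were lost without either Folr1-/- replicate (0.72 and 0.98 for Pdia4, 0.56 and 0.47 for Phgdh), and that of Phgdh also without Folr1+/+ replicates 2 or 3 (0.43 and 0.50). Immediate early and heat shock genes had 1 of 13 higher (median 0.09, adjusted p = 0.53, 1 adjusted over the list alone), and retinoic acid genes 2 higher and 3 lower of 10 (median -0.11, adjusted p = 0.53, the same adjusted over the list alone), with Rbp4 at 2.28 ± 0.15 and Crabp2 at -1.88 ± 0.17. Extracellular matrix genes had 2 higher and 2 lower of 22 (median 0.13, mean -0.0045, camera direction higher, adjusted p = 0.87, 3 higher and 2 lower adjusted over the list alone), among them Sparc at 0.84 ± 0.15 and Col3a1 at -1.01 ± 0.15. Hedgehog targets had 1 higher and 3 lower of 6 (median -0.33, adjusted p = 0.42, fry adjusted p = 0.031, range 0.031 to 0.73, the same adjusted over the list alone), with Gas1 at -1.53 ± 0.19 and Foxa2, also in the epithelium list, at 1.10 ± 0.18. WNT targets had 2 higher of 7 (median -0.17, mean 0.25, camera direction higher, adjusted p = 0.64, fry adjusted p = 0.047, range 0.047 to 0.75, 2 higher and 1 lower adjusted over the list alone), led by the antagonist gene Dkk1 at 1.61 ± 0.18, and the median was -0.33 without Folr1+/+ replicate 1 and -0.041 without Folr1+/+ replicate 2. FGF targets gave 0 of 6 (median -0.08, adjusted p = 0.63, 0 adjusted over the list alone), the smallest unadjusted p values being those of Dusp6, Spred2 and Spry2, with adjusted p of 0.068, 0.42 and 0.55. Dusp6 passed with array weights (limma adjusted p = 0.041), with the Actb 3'/5' ratio as a covariate (0.042) and without Folr1+/+ replicate 2 (0.047). Without Folr1-/- replicates 1 and 2, Spred2 had -0.0094 and -0.42 and Spry2 0.12 and -0.59. Cytosolic ribosomal proteins gave 1 higher and 1 lower of 45 (median -0.03, mean -0.0017, camera direction higher, adjusted p = 0.99, 1 lower adjusted over the list alone).

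Neighbours of Folr1 on chromosome 7 had 1 gene higher, Stard10, 1 lower, Dhcr7, and 13 of 15 not passing (median -0.01, mean 0.05, camera direction higher, adjusted p = 0.80, 0 higher and 1 lower adjusted over the list alone). Dhcr7, which is also a cholesterol synthesis gene, had a fold change of -0.91 ± 0.17. Stard10 had 0.83 ± 0.25, a call lost without either Folr1-/- replicate (1.095 and 0.56) and without Folr1+/+ replicates 1 or 3 (0.57 and 0.94). Anapc15 and Rhog had fold changes of 0.42 ± 0.17 and 0.45 ± 0.18 (adjusted p = 0.13 and 0.11), and without Folr1-/- replicate 1 Anapc15 had 0.26.

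**Figure D2:**
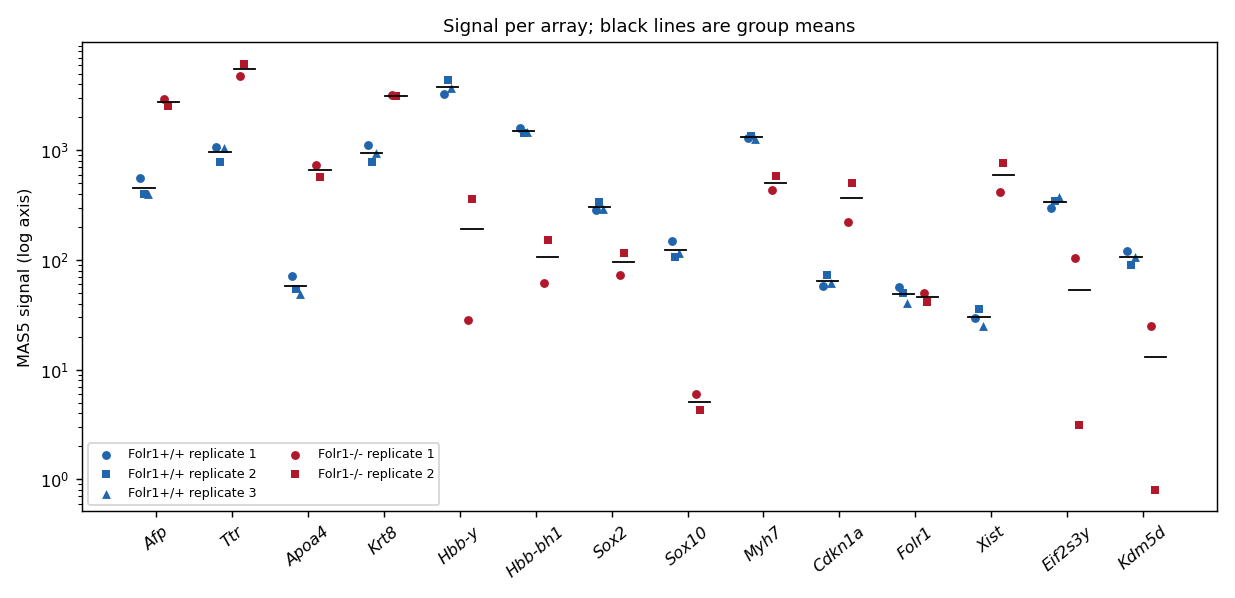
MAS5 signal on a log axis for 14 genes on the horizontal axis, with Folr1+/+ arrays in blue, Folr1-/- arrays in red, a marker shape per replicate and black lines at the group means. Hbb-y lies at 28.4 and 358 in the Folr1-/- arrays, Folr1 overlaps between the groups, and Eif2s3y differs between the Folr1-/- replicates, at 104 and 3.13.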

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

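Among probe sets with several gene symbols or none, which only the test of all probe sets uses, 128 of 1058 tested passed the adjusted p threshold of 0.05. They were flagged because they are a signal in data outside the main measurement. Testing every probe set gave 1527 changed of 13576, and 1207 of 8335 genes had at least 1 changed probe set, 5 of them with probe sets changed in both directions.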

How the results depend on the processing

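Of the 108 named genes past the threshold and the 14 list calls, none changed direction in a setting in which it was tested. At the 60th percentile 24 of the named genes and the erythroid and somite lists were not tested, and with the mean of probe sets 6 of the named genes were not. With all 5 arrays, between 747 (no filter) and 1376 (array weights) genes changed at an adjusted p under 0.05. Among the named calls tested, 21 were lost with no filter, 12 with the mean of probe sets and 0 to 7 in the other settings with all arrays, and 8, 8 and 22 without each Folr1+/+ replicate and 31 and 23 without each Folr1-/- replicate. The number of arrays limits the precision: leaving out 1 array gave 369 to 1007 changed genes, 225 to 566 higher and 144 to 441 lower, where a lone Folr1-/- array is assumed to vary like the others. Fewer arrays leave fewer degrees of freedom. Dim signals are limited by background.

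With no filter, 311 genes were lower. More genes shared both the intensity trend and the adjustment there, and their parts were not told apart. With an adjusted p under 0.10, 795 were lower, as the looser threshold sets. Lists past the threshold numbered 8 with the filter at the 60th percentile, which leaves fewer genes, and 0 with an estimated correlation. A higher correlation cannot account for every loss, as the neural progenitor, somite, anterior Hox and oxidative phosphorylation lists had estimates under the preset 0.01. Their estimates were -0.066, -0.116, -0.094 and 0.0050, while the other lists that passed had estimates above 0.01. Camera also uses the 3 residual degrees of freedom with an estimated correlation. With a preset correlation it takes them from the number of tested genes. For the neural progenitor list, the unadjusted camera p was 6.4e-08 with the preset and 0.011 with the estimated correlation. The losses thus reflect the few arrays too, and the parts were not told apart. The Folr1 fold change changed sign. It was 0.025 with median centring, which moved every fold change up by the same amount. The median fold change over tested genes was 0.071 with it and -0.020 without it. Over the arrays left out, Folr1 had -0.17 to 0.032, and the cause was not tested. Without the X- and Y-linked genes, added after seeing the data, 12 list calls were kept.

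The medians of lists without a call changed sign as follows. The cause was not tested, except that median centring moved all genes up alike. With no filter, posterior Hox genes had -0.038 and WNT targets 0.068. With the 60th percentile, folate genes had 0.061 and FGF targets 0.054. With quantile normalization, ribosomal proteins had 0.13 and Folr1 neighbours 0.018. With median centring, folate genes had 0.034, nucleotide synthesis 0.057, FGF targets 0.010, ribosomal proteins 0.061 and Folr1 neighbours 0.080. With array weights, ribosomal proteins had 0.0029 and Folr1 neighbours 0.057, and with the mean of probe sets tail bud genes had 0.0665. Leaving out 1 array gave -0.11 to 0.095 for folate genes, -0.039 to 0.12 for immediate early genes, -0.060 to 0.092 for Folr1 neighbours, -0.0555 to 0.030 for ribosomal proteins, -0.16 to 0.078 for FGF targets, -0.25 to 0.0047 for retinoic acid genes, -0.011 to 0.14 for extracellular matrix and -0.59 to 0.12 for the gene Spry2.

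With the replicate number as a block, 899 genes changed, 824 of them among the 1114, and 14 lists passed, with 1 residual degree of freedom and a Folr1 fold change of -0.17. The labels state no pairing. After removing group means, correlations of Folr1-/- replicate 1 with Folr1+/+ replicates 1 to 3 were 0.019, 0.056 and -0.094. Those of Folr1-/- replicate 2 were -0.019, -0.056 and 0.094. They mirror the first by construction, since 2 arrays lie equally far from their mean, and add nothing.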

Other observations

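A pair of further gene lists was chosen after the values were seen, around genes already known to change, so their counts and values are given without a list test. Of 24 tested genes for lysosomal proteins, 11 rose and 13 did not pass in the arrays labelled Folr1-/- (median 0.52). They include the protease genes Ctsh (2.81, also in the endoderm list), Lgmn (2.49), Ctsc (1.60), Ctsb (1.49) and Ctsl (1.14) and the hexosaminidase gene Hexa (1.25). Of 13 tested fatty acid synthesis genes, 5 fell, 1 rose and 7 did not pass (median -0.45). The desaturase genes Scd1, Fads1, Fads2 and Scd2 fell by 1.86, 1.26, 1.05 and 0.85 on the log2 scale and the elongase gene Elovl6 by 0.72, while Elovl1 rose by 0.89.

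The tests on RNA quality, yolk sac with and without blood, dilution, developmental stage, the splits of the arrays and the Folr1 transcript were chosen after seeing the results. The tests on sex, X-linked genes and DNA near Folr1 were written before their values were seen, except that the fractions on the signals and their use in the test on sex were added after.

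For the higher endoderm genes, a difference in RNA quality was tested with the Actb 3'/5' ratio as a covariate, and their median fold change stayed at 2.24. The ratio overlapped between the groups (21.1, 39.5 and 29.1 in Folr1+/+ against 30.5 and 22.8 in Folr1-/-). The covariate could therefore hardly move the fold change. A difference in this ratio does not account for the higher endoderm genes, but other differences in RNA quality or amplification were not tested. Whole yolk sac with its usual blood, carried along at dissection, would raise erythroid genes, but the erythroid score differed by -1.56, with a gap between the groups of 1.30 and a largest SD within a group of 0.27. Yolk sac endoderm carried along without blood cannot be told apart from more endoderm in the embryo, as the endothelium score, which differed by -0.1, does not separate them. Of 16 trophoblast and decidua genes on the array (median 0.23, 6 negative) only Plac1 and Prl8a2 were bright enough to test, and both rose, but Plac1 is X-linked, Prl8a2 differed between the Folr1-/- replicates (143 and 34.6), and the labels have decidua and chorion removed, so these genes do not settle it.

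For the lower neural, erythroid and somite genes, dilution was tested by the neural progenitor score minus the endothelium score. Uniform dilution by RNA of tissue with neither kind of cell would leave it much the same in both groups. It differed by -0.946, with a gap of 0.905 and a largest SD of 0.04, which speaks against such dilution alone. Tissue with its own endothelium could lower the neural score and keep the endothelium score, so the test cannot count against dilution by such tissue. An earlier developmental stage of the Folr1-/- embryos cannot be told apart from an effect of the genotype, since the posterior Hox genes, with a median of 0.2, did not pass as a list in either direction. That median was 0.36 without Folr1-/- replicate 1, 0.040 without Folr1-/- replicate 2 and -0.038 with no filter, so it does not settle the question. An earlier stage would also keep or raise tail bud genes. These had a median of -0.24, with 3 higher, 3 lower and 5 not passing (camera adjusted p = 0.53, fry adjusted p = 0.047). As they went both ways, they do not settle it either.

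For the sex-linked genes, a sex difference as the cause of the other shifts was tested by the shift in Folr1-/- replicate 1 as a fraction of that in replicate 2. On the log2 scale and on the signals it was 0.37 and 0.70 for Eif2s3y, 0.55 and 0.77 for Kdm5d and 0.79 and 0.53 for Xist, against 1.06 and 0.988 for the endoderm list, 1.09 and 1.45 for neural progenitors and 1.28 and 1.09 for erythroid genes. Each list lies above the sex-linked genes. On the log2 scale the jackknife SE over genes is 0.0382 for endoderm, 0.126 for neural progenitors and 0.197 for erythroid genes. This puts each list more than 2 SE above the bound of 0.8. On the signals the SE is 0.122, 0.337 and 0.0226, which leaves endoderm and neural progenitors, but not erythroid genes, within 2 SE of that bound. Each fraction also compares 1 array with 1 other, so sex as a cause of the other shifts cannot be told apart from genotype. X-linked genes changed 1.42 times as often as autosomal genes (95% interval 1.11 to 1.83), under the factor of 2 set beforehand. That factor does not bear on whether they made up the change. With 52 changed and 196 not, the tested X-linked genes are too few to make up most of the 1109 changed genes with an X-linked or autosomal position.

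The labelled grouping was the only 1 of 10 splits of the arrays to give 1114 changed genes. Each other split gave 0 with limma, with up to 904 at an unadjusted p under 0.05, and 10 splits are too few for a share under 0.05. The 200 tested genes nearest to Folr1 changed 1.12 times as often as other autosomal genes (33 genes, 16.5% against 14.7%, 95% interval 0.819 to 1.54, Fisher p = 0.478). The Folr1 fold change of -0.0662 lay under that of the lowest endoderm gene, Lrp2, at 0.96 ± 0.19 (SE). The mean of Folr1 lay at the 47.9th percentile of all genes, where its probe set may measure background. This therefore does not tell whether the Folr1 transcript is intact.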
